A study of Arabidopsis thaliana with 9 samples.

How the data were processed

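Root RNA of Arabidopsis thaliana was measured on 9 Affymetrix ATH1 arrays, 3 for each of 3 lines: the wild type Col-0 and the lines labelled cngc1-3 and cngc19 in the same background. CNGC genes encode cyclic nucleotide-gated channels, which let cations through plant cell membranes. Per the labels' protocols, seedlings moved from agar to aerated hydroponics at day 18, stayed there for 7 days and were harvested at day 25, at growth stage 3.90, with the roots of 20 to 30 plants bulked into a tube. Total RNA was purified with a column kit and labelled by the array maker's one-cycle method, per the labels' protocols. The series title speaks of caesium toxicity, but the labels list no caesium treatment for any of the 9 arrays, and the nutrient solution is listed without caesium. Nothing in the labels says how the 3 tubes of a line relate to separate cultures, so p-values measure only the spread between these tubes, which may in part be technical.

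The deposited values are signal intensities on a linear scale, made with MAS5 and GCOS per the submitters' processing notes. MAS5 combines the perfect-match and mismatch probes of a probe set into a single signal and scales each array to a common trimmed mean. The deposited intensity table held 22810 probe sets, of which 64 were the maker's controls and 22746 were others. The mean signal after trimming 2% at each end lay between 98.9 and 99.6 on the 9 arrays, so the deposited scaling was kept. Such scaling makes the average brightness of arrays alike whatever the amount of target on them. No detection calls were used here, and the number of arrays limits the precision. No pair of arrays held identical values.

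Groups and replicate numbers came from the sample titles. Signals were analysed as log2(value + 16), so a fold change of a dim probe set is understated. Probe sets whose mean log2 value over the 9 arrays was at or above the 40th percentile were tested, 13648 in all. This filter and the shared spread include all 3 Col-0 arrays. Lines were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), with all 9 arrays in one model, two-sided, at a Benjamini-Hochberg adjusted p under 0.05. The model has 6 residual degrees of freedom. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

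Probe sets were named through the platform's annotation, which gave 1 gene symbol for 13513 probe sets and several for 503, while 8730 are unnamed here. Of the first, 13436 were brought up to date through a RefSeq gene table (assembly TAIR10.1) and 77 kept the platform's symbol. Of the tested probe sets, 7419 had 1 symbol. None of the 20 CNGC family genes had a named probe set here, so CNGC1 and CNGC19, the genes the line names point to, were not analysed here and the line labels could not be checked through them.

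Of 28 gene lists fixed before the data were examined, 8 had 5 or more tested genes: calcium sensors, photosynthesis as a marker of shoot tissue, glutathione S-transferases, class III peroxidases, cell wall loosening and extensins, phenylpropanoids and flavonoids, cell cycle and replication, and auxin response and transport. The other 20 lists were too small to test, mostly because few of their genes had a named probe set (1 of 47 for potassium transport). The tested lists are parts of their families too. Tested were 10 of 55 matched photosynthesis genes, 11 of 51 glutathione S-transferases, 6 of 64 calcium sensors and 8 of 60 auxin genes. Counts of list genes below refer to the tested ones. Lists were tested with limma's camera (preset correlation 0.01), 1 probe set per gene, adjusted over the 8 lists within a comparison. Camera with an estimated correlation and fry were run beside it.

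Named genes followed a rule fixed before the data were examined. For each mutant against Col-0 these were up to 12 genes per direction with the largest change past the threshold and no overlap between the arrays of both lines. Where fewer passed, places up to 6 per direction went to the genes of smallest unadjusted p without overlap. The same rule with up to 6 genes per direction held for cngc1-3 against cngc19. In each gene list, up to 4 members with the smallest unadjusted p could be named. Genes chosen after their values were seen are marked as such.

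Alternatives fixed before the data were examined were pseudocounts of 1 and 64, no filter and a filter at the 60th percentile, quantile normalization, centring each array on its median, eBayes without trend and with robust hyperparameters, array weights, an adjusted p under 0.1, the replicate number as a block, only the lines compared, each array left out in turn, and the other list tests. Leaving out 2, 3 or 4 arrays together was added after seeing the data. The procedure was tested on simulated data for cngc1-3 against Col-0, with 13648 genes of which 200 were changed. With the spread of all 9 arrays it recovered 0% of genes changed by 1 on the log2 scale, 17.9% of those changed by 2 and 75.8% of those changed by 4. With the spread of the 6 mutant arrays it recovered 26.9%, 76.1% and 98.5%. With that of replicates 1 and 2 of both mutant lines it recovered 77.6%, 97.0% and 100%. Unchanged genes called were 2, 4 and 16 in these 3 cases. All 3 lines were simulated with the same spread, while the real Col-0 arrays differed more than the mutant arrays. The rates are therefore not those of the real comparison.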

Results

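Roots of the wild type Col-0 and of the lines cngc1-3 and cngc19 were profiled on 3 ATH1 arrays each. The lines carry the names of genes for cyclic nucleotide-gated channels, which conduct cations such as potassium and calcium. The comparisons ask which root transcripts differ between each line and the wild type, and between both lines. Values below are MAS5 signals as deposited, scaled to a trimmed mean near 100 on each array, and fold changes are on the log2(signal + 16) scale. Values of a line are means ± SD with n = 3.

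The 3 Col-0 arrays did not resemble each other. Across the 13648 tested probe sets, Col-0 replicate 2 correlated with the 7 arrays outside Col-0 replicates 2 and 3 at r between -0.04 and -0.02, and Col-0 replicate 3 at r between 0.26 and 0.38. Col-0 replicate 1 correlated with cngc19 replicate 3 at r = 0.950 and with the other mutant arrays at 0.764 to 0.878. Replicates 1 and 2 of both mutant lines correlated with each other at 0.964 to 0.985. These correlations are across probe sets, which are not independent replicates.

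**Figure D1:**
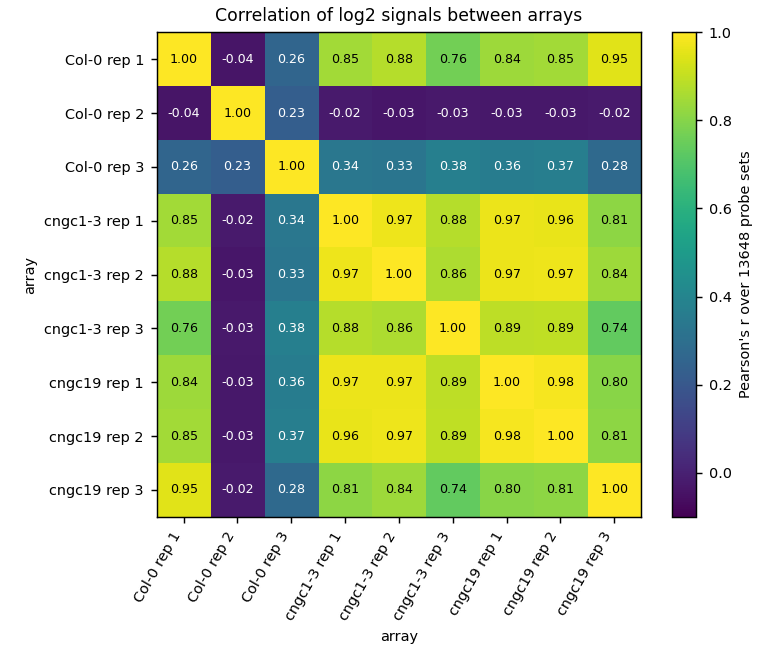
Pearson correlation of log2 signals over the tested probe sets for every pair of the 9 arrays, with both axes listing arrays by line and replicate. Col-0 replicate 2 lies near 0 with the mutant arrays, Col-0 replicate 3 reaches at most 0.38 with any array, and Col-0 replicate 1 is closest to cngc19 replicate 3 (r = 0.950).

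Control probe sets set some arrays apart as well. The spiked-in controls, which are bacterial and phage transcripts added to the hybridisation mix, were 15.8 times the median of the other arrays on Col-0 replicate 2 and 6.80 times on Col-0 replicate 3. On the other 7 arrays this ratio lay between 0.658 and 1.54. The ratio of 3' to 5' signal, which rises when RNA is degraded or copied incompletely, was 6.37 for GAPDH and 199.7 for actin on cngc1-3 replicate 3. On the other 8 arrays it lay between 0.240 and 2.81 for GAPDH and between 1.34 and 5.81 for actin.

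**Figure D2:**
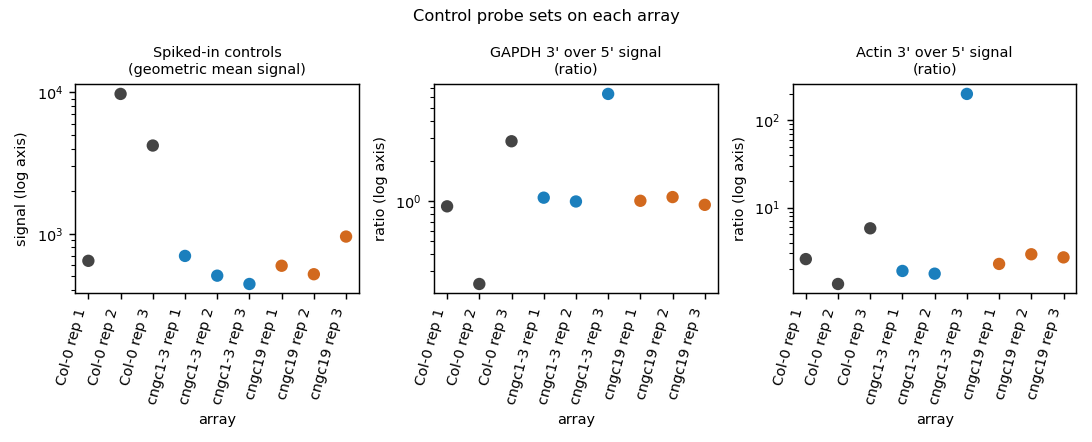
Geometric mean signal of the spiked-in controls and the 3' over 5' signal ratios of GAPDH and actin on each array, each on a log axis, with points coloured by line. The spiked-in controls are highest on Col-0 replicates 2 and 3, and both ratios are highest on cngc1-3 replicate 3 (6.37 and 199.7).

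In cngc1-3 against Col-0, the genes of smallest p lay 2.34 to 3.75 log2 units higher or 1.66 to 3.25 lower in the mutant, but none passed the test. AT3G18760 had a signal of 530.9 ± 59.0 in cngc1-3 and 62.7 ± 81.5 in Col-0, a log2 fold change of 3.29 ± 0.64 (SE). AT4G33560, of a wound-responsive family, had 478.6 ± 128.7 against 23.12 ± 18.18, a log2 fold change of 3.75 ± 0.77 (SE). AT5G37990, a methyltransferase-family gene, had 285.7 ± 72.0 against 39.1 ± 43.3. AT2G34050, AT3G09890 and AT3G59650 were higher in cngc1-3 by 2.44, 2.49 and 2.34 log2 units. Lower values were found for AT1G67865, with 10.1 ± 3.94 in cngc1-3 against 272.5 ± 195.9 in Col-0, and for AT5G40450, with 65.9 ± 57.5 against 483.7 ± 96.4. AT4G36980, AT2G17930, AT3G24480 and AT1G44830 had log2 fold changes of -2.28, -1.79, -1.87 and -1.66. AT3G24480 encodes a leucine-rich repeat extensin of the cell wall, and AT1G44830 a transcription factor of the ERF/DREB family. The 3 arrays of cngc1-3 lay on the same side of the 3 Col-0 arrays for each of these 12 genes, as the naming rule requires. Against Col-0 replicate 1 alone, the genes that were higher lay 1.35 to 3.11 log2 units higher and the others had differences of -4.29 to -0.93, with AT3G18760 higher by 1.66.

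No probe set passed in this comparison (limma, 0 of 13648, smallest adjusted p = 0.181), while 3301 had an unadjusted p under 0.05. In 1793 probe sets all 3 cngc1-3 arrays lay above and in 1547 all lay below the 3 Col-0 arrays, together 24.5% of those tested. Chance gives 10% if the arrays compared are interchangeable. The 2 Col-0 arrays with raised spiked-in controls stood apart, so the excess cannot be credited to the line. The count of calls rested on single arrays: it was 4810 without Col-0 replicate 1, when the wild type consists of the 2 arrays with raised spiked-in controls, and 14 without cngc19 replicate 3. Array weights gave 1228, and leaving out both Col-0 arrays with raised spiked-in controls, an alternative added after seeing the data, gave 0 with 1156 at an unadjusted p under 0.05. In that setting the wild type is 1 array and its spread is taken from the mutant arrays.

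**Figure D3:**
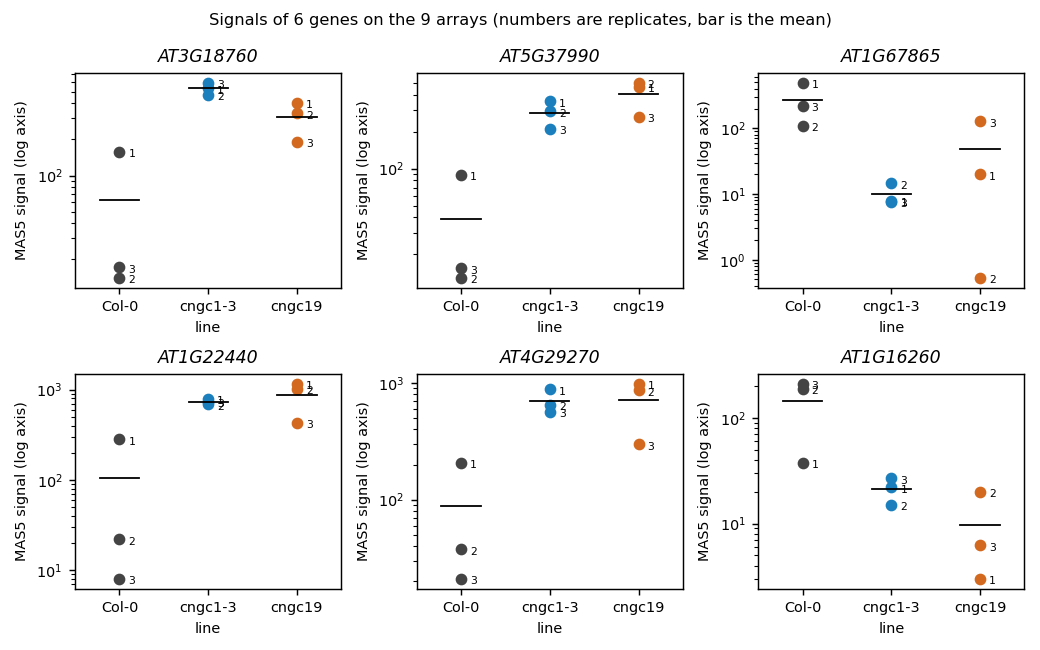
MAS5 signal on a log axis for 6 of the named genes in each line, with points for single arrays numbered by replicate and bars for the arithmetic mean of 3 arrays. AT3G18760, AT5G37990, AT1G22440 and AT4G29270 lie higher in both mutant lines than on any Col-0 array, with Col-0 replicate 1 nearest to the mutants, and AT1G16260 lies lower in both, while AT1G67865 overlaps between Col-0 and cngc19. None of these differences passed the test.

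Among the glutathione S-transferases, enzymes that conjugate glutathione to reactive compounds, 8 of 11 genes were higher in cngc1-3 than in Col-0, none passed over all probe sets, and 2 passed when adjusted over the list alone. These were GSTU25, at 499, 528 and 637 on the cngc1-3 arrays against 46.5, 16.7 and 31.7 in Col-0 (log2 fold change 3.62), and GSTU22, at 862, 583 and 713 against 284, 25.4 and 58.2 (2.8995). The list as a whole did not pass (camera, adjusted p = 0.196), and its median of 0.45 became 0.21 without Col-0 replicates 2 and 3. Its median on the Col-0 arrays was -0.09, -0.65 and -1.15 log2 units from its median over the 7 arrays other than Col-0 replicates 2 and 3. Among class III peroxidases, cell wall enzymes that use hydrogen peroxide, 4 of the 5 tested genes were higher in cngc1-3 and 2 passed when adjusted over the list alone. AT5G64120 had a log2 fold change of 4.33 and AT5G66390 of 2.96. The list did not pass (camera, adjusted p = 0.106), and its median was 0.66 on Col-0 replicate 1 but -4.59 on both other Col-0 arrays. Without these 2 arrays the direction turned, with a median of -0.59 and 2 of 5 genes higher (adjusted p = 0.516).

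All 10 photosynthesis genes, which mark shoot tissue, were lower in cngc1-3 than in Col-0 with a median log2 fold change of -1.11, and none passed, nor did the list (camera, adjusted p = 0.196). PRK, an enzyme of the Calvin cycle, had signals of 6.25, 366 and 1441 on the Col-0 arrays and 43.2, 38.2 and 111 in cngc1-3, and LHCB4.3, a light-harvesting protein, had 20.8, 221 and 196 against 29.7, 31.2 and 63.96. The median of the list was 4.64 log2 units above that level on Col-0 replicate 3, 0.97 above it on Col-0 replicate 2 and at -1.39 on Col-0 replicate 1. Without Col-0 replicates 2 and 3 the direction turned: all 10 genes were higher in cngc1-3, with a median of 1.68 (camera, adjusted p = 2.5e-05, and adjusted p = 0.544 with an estimated correlation). These p-values set a single Col-0 array against 3 arrays and borrow its spread from the mutant arrays.

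The other 5 lists did not pass in cngc1-3 against Col-0, and none of their genes passed when adjusted over the list alone. Calcium sensors, the proteins that bind calcium and relay its signals, had 2 members higher and 4 lower (median -0.17, adjusted p = 0.941). The calmodulin-like genes CML42 and CML41 had log2 fold changes of 1.87 and -1.48. Cell wall loosening genes and extensins had 11 members higher and 9 lower (median 0.25, adjusted p = 0.720), among them XTH19 at 2.31 and EXPB3 at 1.403. Phenylpropanoid and flavonoid genes had 3 higher and 2 lower (adjusted p = 0.941), with a median of 0.14 and a mean of 0.06 while the test pointed down. DFR, an enzyme of anthocyanin synthesis, was at -1.70. Cell cycle genes had 4 higher and 1 lower (median 0.36, adjusted p = 0.720), with the Aurora kinase gene AUR2 at 0.88. Auxin genes had 4 in each direction (median 0.03, adjusted p = 0.941), with GH3.17 at 2.65 and IAA34 at -1.57. Without Col-0 replicates 2 and 3 the cell wall median became -0.26 with 7 of 20 genes higher, the phenylpropanoid median -0.06 with 2 of 5 higher, and the medians of calcium sensors, cell cycle and auxin genes -0.88, 0.34 and 0.19. XTH19, GH3.17 and IAA34 then changed sign.

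In cngc19 against Col-0, the genes of smallest p lay 1.84 to 3.65 log2 units higher or 1.56 to 2.99 lower in the mutant, and none passed the test. AT1G22440, of an alcohol dehydrogenase family, had a signal of 868.1 ± 388.2 in cngc19 and 103.9 ± 154.1 in Col-0, a log2 fold change of 3.65 ± 0.83 (SE). AT5G37990 had 408.6 ± 126.9 against 39.1 ± 43.3, a log2 fold change of 3.167 ± 0.549 (SE). AT4G29270, of an acid phosphatase family, had 716.3 ± 365.9 against 88.8 ± 103.5, and ARPN, a plantacyanin, 440.1 ± 164.2 against 70.0 ± 94.7. AT2G18210 and AT3G25640 were higher by 2.31 and 1.84 log2 units. Lower values were found for AT5G58980, of a ceramidase family, with 9.24 ± 2.84 against 262.5 ± 215.0, and for AT1G16260, of the wall-associated kinase family, with 9.71 ± 8.97 against 144.4 ± 93.3. Both are dim: on Col-0 replicate 1 they had 39.1 and 37.3, below that array's median signal of 42.1. Their high signals came from Col-0 replicates 2 and 3 (280.4 and 467.9 for AT5G58980, 187.4 and 208.4 for AT1G16260), where the array medians were 63.9 and 66.3. AT1G65370, AT4G36520, AT1G24420 and AT1G03400 had log2 fold changes of -2.04, -1.80, -1.56 and -2.09. Against Col-0 replicate 1 alone, the genes that were higher lay 1.15 to 1.96 log2 units higher and the others had differences of -1.80 to -1.08, with AT5G58980 at -1.13 where the mean of 3 Col-0 arrays gave -2.99. The direction of these differences is fixed by the naming rule, which requires no overlap with any Col-0 array, so only their size is informative.

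No probe set passed in this comparison either (limma, 0 of 13648, smallest adjusted p = 0.273), while 2464 had an unadjusted p under 0.05. All 3 cngc19 arrays lay above the 3 Col-0 arrays in 1017 probe sets and below them in 939, together 14.3%. Chance gives 10% if the arrays are interchangeable, which Col-0 replicates 2 and 3 were not, so this excess cannot be credited to the line either. The count was 4448 without Col-0 replicate 1, 11 without cngc19 replicate 3 and 1047 with array weights, and it stayed at 0, with 365 at an unadjusted p under 0.05, when Col-0 replicates 2 and 3 were left out after seeing the data. Of the 14 and 11 calls without cngc19 replicate 3, 9 were shared by both comparisons, among them GSTU25 and AT5G64120. In all these calls the left-out array lay near the Col-0 signals and far below cngc19 replicates 1 and 2. On cngc19 replicates 1, 2 and 3, GSTU25 had 651, 619 and 36.3, and AT5G64120 had 1071, 1108 and 30.4. Both comparisons also use the same Col-0 arrays, so the shared calls do not show a response common to both lines.

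The class III peroxidases passed as a list in cngc19 against Col-0 (camera, adjusted p = 0.029), with all 5 tested genes higher and a median log2 fold change of 2.82. The names of this list matched 16 genes, of which 7 had a named probe set, so these 5 stand for only part of the family. The call was lost with an estimated correlation (adjusted p = 0.625 with an estimated correlation) and with fry (adjusted p = 0.189). No member passed over all probe sets, and 3 passed when adjusted over the list alone. AT5G64120 had signals of 1071, 1108 and 30.4 on the cngc19 arrays against 50.2, 14.4 and 5.78 in Col-0, AT5G66390 had 682, 723 and 460 against 488, 5.98 and 11.1, and Prx37 had 634, 646 and 1551 against 1029, 57.0 and 8.91. The list's median was 0.66 on Col-0 replicate 1 and -4.59 on both other Col-0 arrays. Without these 2 arrays the direction turned, with a median of -0.25 and 2 of 5 genes higher (adjusted p = 0.825).

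**Figure D4:**
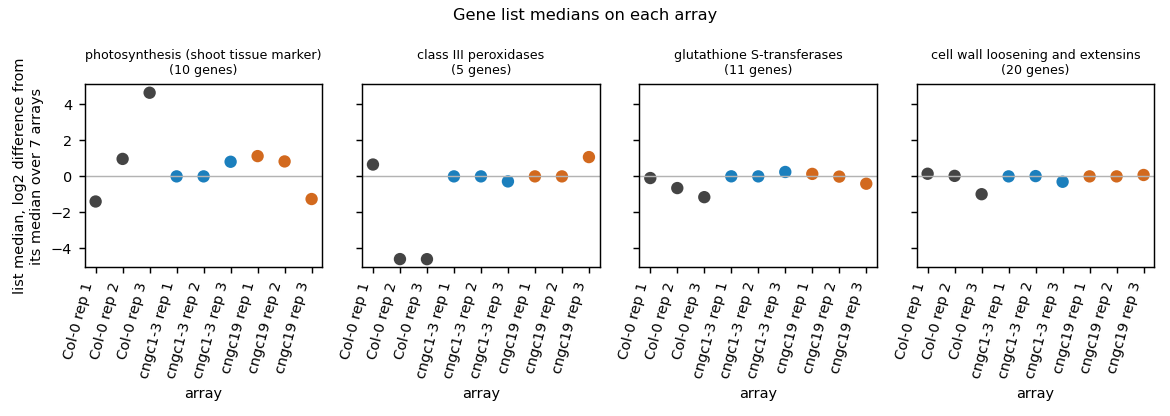
Median of 4 gene lists on each array, as the log2 difference from the list's median over the 7 arrays other than Col-0 replicates 2 and 3, with points coloured by line. The photosynthesis median reaches 4.64 on Col-0 replicate 3, and the peroxidase median is -4.59 on Col-0 replicates 2 and 3 but 0.66 on Col-0 replicate 1.

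All 10 photosynthesis genes were lower in cngc19 than in Col-0 (median -1.19, camera adjusted p = 0.155), with PRK at -1.57 and LHCB4.3 at -1.35 on the log2 scale. Without Col-0 replicates 2 and 3, all 10 were higher with a median of 1.73 (adjusted p = 3.8e-08, and adjusted p = 0.477 with an estimated correlation), again with a single Col-0 array whose spread is borrowed from the mutant arrays. Of the glutathione S-transferases 7 of 11 were higher (median 0.50, adjusted p = 0.292) and none passed when adjusted over the list alone. GSTU25 had signals of 651 and 619 on cngc19 replicates 1 and 2 and of 36.3 on replicate 3, and GSTU22 had 643, 571 and 204. Calcium sensors had 3 genes higher and 3 lower (median 0.09, adjusted p = 0.859), with CML42 at 1.69. Cell wall genes had 12 higher and 8 lower (median 0.21, adjusted p = 0.718), with the expansin gene EXPA4 at 3.06. Phenylpropanoid genes had 3 higher and 2 lower (adjusted p = 0.859), with a median of 0.44 but a mean of -0.02 and a test that pointed down, and DFR was at -1.80. Cell cycle genes had 4 higher and 1 lower (median 0.27, adjusted p = 0.859), with the lower one, PRL, at -0.82. Auxin genes had 5 higher and 3 lower (median 0.23, adjusted p = 0.859), with GH3.17 at 2.99. Without Col-0 replicates 2 and 3 the medians of 3 of these lists turned, to -0.51 for calcium sensors (2 of 6 genes higher), to -0.20 for cell wall genes (9 of 20) and to -0.20 for phenylpropanoids (1 of 5). Those of glutathione S-transferases, cell cycle and auxin genes became 0.05, 0.25 and 0.12.

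Between cngc1-3 and cngc19, the genes of smallest p lay 0.81 to 1.71 log2 units higher or 1.16 to 1.87 lower in cngc1-3, and none passed the test. AT3G09470 had a signal of 347.6 ± 27.9 in cngc1-3 and 179.0 ± 48.2 in cngc19, a log2 fold change of 0.93 ± 0.42 (SE), by the probe set of smallest p of its 2. AT4G22380 had 247.3 ± 36.2 against 127.9 ± 46.2, and AT2G04800 had 282.0 ± 48.4 against 103.2 ± 80.3. AT2G41730, AT1G73780 and AT3G18510 were higher in cngc1-3 by 1.32, 1.03 and 0.81 log2 units. Lower in cngc1-3 were AT5G10770, of an aspartyl protease family, with 8.53 ± 3.44 against 72.9 ± 45.0 (log2 fold change -1.74), and AR781 with 52.6 ± 8.35 against 148.0 ± 80.0 (-1.16). The chloroplast ribosomal protein gene rpl22 was at 68.0 ± 37.4 in cngc1-3 and 247.2 ± 51.5 in cngc19. AT1G20280, AT2G15560 and AT5G45430 had log2 fold changes of -1.22, -1.87 and -1.38. In each of these genes except rpl22, cngc19 replicate 3 was the cngc19 array farthest from cngc1-3, which enlarges the differences given. AR781, for example, had 95.5, 108.5 and 240.1 on cngc19 replicates 1, 2 and 3. On cngc19 replicates 1, 2 and 3 the signals were 38.2, 29.4 and 415.9 for AT2G15560. They were 144.4, 154.5 and 10.7 for AT2G04800, and 169.2, 168.5 and 13.7 for AT2G41730. For rpl22 they were 239.5, 302.2 and 199.9, so its difference does not rest on that array. No probe set passed (limma, 0 of 13648, smallest adjusted p = 1.000), and 13 had an unadjusted p under 0.05. The arrays of both lines did not overlap in 8.26% of probe sets, where chance gives 10%. The model of all 9 arrays takes part of its spread from the Col-0 arrays, which are not in this comparison. With only the 2 lines compared, 232 had an unadjusted p under 0.05 and again 0 passed (limma). Both counts lie below the share of 0.05 that chance would give. The lack of calls therefore does not show that the lines are alike. Array weights gave 9 calls, and leaving out both Col-0 arrays with raised spiked-in controls together with replicate 3 of both mutant lines, after seeing the data, gave 106. Over all 3 lines the F-test called 0 probe sets (smallest adjusted p = 0.334), with 2037 at an unadjusted p under 0.05.

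None of the 8 lists passed between cngc1-3 and cngc19, and none of their genes passed when adjusted over the list alone. The medians were -0.26 for calcium sensors (adjusted p = 0.767), 0.12 for glutathione S-transferases (0.767), -0.31 for class III peroxidases (0.935), 0.10 for phenylpropanoids (0.767) and 0.09 for the cell cycle (0.767). They were -0.02 for photosynthesis (0.935) and -0.04 for cell wall genes (0.935), both with a test that pointed up, and 0.00 for auxin genes (0.935) with a mean of -0.08 and a test that pointed down.

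The log2 fold changes of both mutants against Col-0 correlated at r = 0.951 over the 13648 probe sets and had the same sign in 90.6%. Both comparisons use the same Col-0 arrays. Unchanged lines were simulated from the spread of each line at each probe set, with a simulated Col-0 mean shared by both comparisons. Their fold changes correlated at 0.869 ± 0.004 (SD, 100 simulations), with the same sign in 82.1%. The Col-0 arrays were simulated as independent, so a departure common to Col-0 replicates 2 and 3 is not in these values. The covariance was 1.11 against 0.525 in the simulations. Without Col-0 replicates 2 and 3 the covariance was 0.369, the correlation 0.898 and the share of the same sign 84.2%, and no simulation was run for that setting. The 3 Col-0 arrays cannot be split so that each part keeps 2, so part of the excess may come from the shared controls. In the model of all 9 arrays there were no calls to share between the comparisons.

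Within cngc19, replicate 3 differed from both other arrays at least 4-fold in 414 probe sets, being higher in 185 and lower in 229. Col-0 replicate 1 lay on the side of cngc19 replicate 3 in 87.2% of these, Col-0 replicate 2 in 56.5%, Col-0 replicate 3 in 37.4% and the 3 cngc1-3 arrays in 3.86% to 5.07%. Examples, chosen after their values were seen, were AT3G57020, of a strictosidine synthase-like family, and the lectin gene JAL33. AT3G57020 had signals of 1688 and 1647 on cngc19 replicates 1 and 2, 17.8 on replicate 3, between 1670 and 1695 on the cngc1-3 arrays and 8.95 on Col-0 replicate 1. JAL33 had 5352 and 4880 on cngc19 replicates 1 and 2, 81.4 on replicate 3 and 1319 on Col-0 replicate 1. In the other direction, the germin-like gene AT3G05950 had 23.4 and 22.7 against 2304 on replicate 3 and 1552 on Col-0 replicate 1, and the zinc finger gene STZ had 68.5 and 65.1 against 1096 and 767.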

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

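The tests in this part were chosen after the result they measure had been seen, except that of a different share of another tissue in cngc19 replicate 3. Both ratios of 3' to 5' signal on cngc1-3 replicate 3, 6.37 for GAPDH and 199.7 for actin, come from control probe sets that no comparison used and lie above every Col-0 array, which is why they stand out. This array correlated with the other mutant arrays except cngc19 replicate 3 at r between 0.864 and 0.894, where replicates 1 and 2 of both lines reached at least 0.964. Degraded or incompletely copied RNA needs an actin ratio far above that of the other cngc1-3 arrays, and the ratio was 199.7 against 1.89 and 1.76, so it remains a candidate explanation for the distance of this array. In 194 probe sets this array was at least 4-fold lower than both other cngc1-3 arrays, and in 6 it was at least 4-fold higher. No biological explanation was tested, since the design names none within a line.

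Col-0 replicates 2 and 3 stood apart from all other arrays. Little labelled plant target on the array would raise spiked-in controls after scaling, and these were 15.8 times the median of the other arrays on Col-0 replicate 2 and 6.80 times on Col-0 replicate 3, so it may account for part of the distance of both. RNA of photosynthetic tissue may be a further part for Col-0 replicate 3, where the photosynthesis list lay 4.64 log2 units above its median over the 7 other arrays and the chloroplast gene psbM had a signal of 40033 against 2151 on Col-0 replicate 1. These tests were made on the arrays in which the pattern was found, and both explanations stay hypotheses. The wild-type genotype alone is argued against, since these 2 arrays share it and correlated with each other at only r = 0.227. Whether it is part of the distance stays open. Col-0 replicate 1 correlated with these 2 arrays at 0.259 at most, below its lowest correlation with a mutant array (0.764), but this is part of the pattern itself and rests on 1 array, which was closest to an array of another line (r = 0.950).

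Replicate 3 of cngc19 was closer to Col-0 replicate 1 (r = 0.950) than to the other mutant arrays (0.735 to 0.841). Degraded RNA is argued against by its GAPDH ratio of 0.939, below both other cngc19 arrays (1.01 and 1.07). Dilution by a large share of another tissue would lower together those abundant root transcripts that the other tissue lacks. The 100 most abundant probe sets shifted by a median of only -0.42 log2 units, while 23 probe sets lay at least 16-fold below both other cngc19 arrays. This shift cannot decide on dilution, since abundant transcripts present in both tissues need not fall. GAPC2, for example, had 3779 on Col-0 replicate 3, where the photosynthesis list was raised, and 4431 on Col-0 replicate 1. A lower share of shoot tissue is not covered by this test and stays open. The photosynthesis median was -1.26 on this array and -1.39 on Col-0 replicate 1, against 1.13 and 0.83 on cngc19 replicates 1 and 2. A wrong line label stays open, since 0 named probe sets of CNGC1 and CNGC19 were at hand to check it. A growth, RNA or hybridisation batch shared with Col-0 replicate 1, which lay on its side in 87.2% of the 414 probe sets (Col-0 replicates 2 and 3 in 56.5% and 37.4%), cannot be told apart from a wrong label, because the labels name no batch.

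The counts of calls were set against other splits of the arrays. For cngc1-3 against Col-0 the real count was 0, as many calls came from 10 of 10 splits of the 6 arrays, and the highest other count was 23. For cngc19 against Col-0 the values were 0, 10 of 10 and 6, and for cngc1-3 against cngc19 they were 0, 10 of 10 and 0. With 10 splits no share under 0.05 can arise. For the F-test over the 3 lines the real count was 0 and 100 of 100 drawn splits, of 280 possible, gave as many, so chance cannot be excluded. A real count of 0 fixes that outcome. Any call came from 15 of the 100 splits, with 66 as the highest. The cause of these calls was not tested.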

How the results depend on the processing

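The settings that leave out 2, 3 or 4 arrays together were chosen after seeing the data, in sequence, and the first and second of them gave 0 calls in every comparison. The numbers of calls below are for cngc1-3 against Col-0, cngc19 against Col-0, cngc1-3 against cngc19 and the F-test, in this order, each 0 in the model of all 9 arrays. They stayed at 0 with other pseudocounts, filters, scalings and variance priors, at an adjusted p under 0.1 and, where it applies, with only the lines compared. Array weights gave 1228, 1047, 9 and 482; their estimation stopped before convergence, and the weights ran from 0.097 for Col-0 replicate 2 to 11.9 for cngc19 replicate 2. Leaving out each array in turn gave 0 to 4810, 0 to 4448, 0 to 0 and 0 to 3748. The highest counts came without Col-0 replicate 1, and 14, 11, 0 and 12 came without cngc19 replicate 3. Without Col-0 replicates 2 and 3 and replicate 3 of both mutant lines the counts were 3434, 3248, 106 and 3042, on 2 residual degrees of freedom. In all settings without Col-0 replicates 2 and 3, Col-0 is represented by replicate 1, assumed to vary like the mutant arrays. All these counts change with the arrays that set the spread, and other causes were not tested. Replicate numbers do not pair the arrays: 3 of 9 same-number pairs of deviations correlated over 0.1 (-0.23 to 0.19), 2 of 9 arrays correlated best with their own number, and with the replicate number as a block the counts were 0 in all comparisons. CNGC1 and CNGC19 were planned as single results and were not run.

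Lists past the threshold in cngc1-3 against Col-0 went from 0 to 1, the photosynthesis list, when 2, 3 or 4 arrays were left out (adjusted p = 0.544, 0.676 and 0.779 with an estimated correlation). In cngc19 against Col-0 the count of 1 became 0 with an estimated correlation, with fry and without a filter, and 2 with quantile normalization, which added the photosynthesis list as lower. It stayed at 1 with 2, 3 or 4 arrays left out, but the list was then photosynthesis, not the peroxidases (adjusted p = 0.477, 0.681 and 0.614 with an estimated correlation). Between cngc1-3 and cngc19 the count went from 0 to 3 with 4 arrays left out (photosynthesis and auxin genes lower, cell wall genes higher in cngc1-3), each with an adjusted p = 0.353 with an estimated correlation. The correlation of both mutants' fold changes, 0.951, was 0.976 with array weights, 0.898, 0.893 and 0.926 with 2, 3 and 4 arrays left out, and 0.912 to 0.975 with each array left out in turn. Over 72 named genes and comparisons and 1626 values, 145 values passed the threshold that had not before, 42 of them with array weights, 41 with 4 arrays left out and 62 with a single array left out, and 20 changed sign, all with 2, 3 or 4 arrays left out. In cngc1-3 the log2 fold change of LHCB4.3 became 0.60, 0.34 and 0.34, that of PRK 1.74, 1.35 and 1.35 and that of XTH19 -0.70, -0.90 and -0.90, with 2, 3 and 4 arrays left out. With 2 left out, GH3.17 became -0.20 and IAA34 0.24. In cngc19 LHCB4.3 became 0.40, 0.40 and 0.46, PRK 1.81, 1.81 and 2.504, and Prx37 -0.25, -0.25 and -0.67. All these changes of sign came in settings where Col-0 replicate 1 stood alone for the wild type. Those of GH3.17 and IAA34 came only with 2 arrays left out, so they also depend on cngc1-3 replicate 3.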

Other observations

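The brightest named transcripts included genes of several functions. PYK10, the beta-glucosidase of endoplasmic reticulum bodies, had a signal of 5047 ± 455 (SD, n = 3) in cngc1-3, 4535 ± 843 in cngc19 and 4398 on Col-0 replicate 1, but 260.8 and 448 on Col-0 replicates 2 and 3. The metallothionein gene MT1C had 3489 ± 403, 3846 ± 888 and 4933, with 273.7 and 422.8 on the other Col-0 arrays. GAPC2, a glycolytic enzyme, had 3441 ± 1356, 3870 ± 403 and 4431, with 852.3 and 3779. These genes were chosen after their values were seen and were not tested as a group.

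Members of fixed lists too small to test gave further values for cngc1-3 against Col-0, none past the threshold over all probe sets. LTI30, a dehydrin of cold and drought responses, was at 1540, 1371 and 2327 on the cngc1-3 arrays against 447, 9.17 and 122 in Col-0, and at 237 on cngc19 replicate 3. The log2 fold change was 3.87 for LTI30 and 1.91 for COR47 of the same list, but -3.17 and -2.77 for its other members COR15A and COR15B. It was 2.23 for PDC2, a pyruvate decarboxylase of fermentation. The ATP sulfurylases of sulfate assimilation went apart, with 2.06 for APS4 and -1.23 for APS3. It was -1.36 for OPCL1, an enzyme of jasmonate synthesis, and -1.83 and -1.88 for the glutamate receptor-like genes GLR1.4 and ATGLR1.2. Several of these rest on Col-0 replicates 2 and 3. Against Col-0 replicate 1 alone the differences were 1.89 for LTI30, 1.22 for COR47, -0.50 for COR15A, -0.24 for COR15B, 1.43 for PDC2, 0.79 for APS4, -1.08 for APS3, -0.97 for OPCL1, -0.43 for GLR1.4 and -0.05 for ATGLR1.2.

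A difference between cngc1-3 and cngc19 was tested as a hypothesis on the 106 probe sets called without Col-0 replicates 2 and 3 and replicate 3 of both mutant lines, 15 higher and 91 lower in cngc1-3. The tests were written before their results were seen and ask whether the left-out array of a line lies on its own line's side. For cngc1-3 replicate 3 this held in 20 of 106 probe sets, or 18.9%, against 42.0% of all tested ones. It held in 13 of the 91 lower and in 7 of the 15 higher ones, so the low share comes from the lower calls. For cngc19 replicate 3 it held in 17 of 106, or 16.04%, against 51.5% of all tested ones. The first value argues against the difference being shared by cngc1-3 replicate 3, unless the quality of this array is the cause (actin ratio 199.7). A check added after these values were seen gave a median shift of 1.24 log2 units toward cngc19 at the 106 probe sets, where 0.61 would reach the midpoint. At uncalled ones of like level the shift was 0.08, which argues against a shift common to probe sets of a level. It cannot decide on degraded or incompletely copied RNA, whose effect need not follow the level. Choosing the 106 by replicates 1 and 2 may also add to the shift. The second value decides nothing, since cngc19 replicate 3 is in doubt by its r = 0.950 with Col-0 replicate 1. Whether the lines differ stays open, since each line then rests on 2 arrays. Photosynthetic transcripts are part of the calls: the median of the photosynthesis list was 0.00 and 0.00 on cngc1-3 replicates 1 and 2 but 1.13 and 0.83 on cngc19 replicates 1 and 2, while both left-out arrays went the other way with 0.81 on cngc1-3 replicate 3 and -1.26 on cngc19 replicate 3, and 5 of the 10 photosynthesis genes, looked at after the values were seen, are among the 91 lower calls. Among the 106 was ICL, the isocitrate lyase of the glyoxylate cycle, chosen after its values were seen, with signals of 54.7 and 59.0 on cngc1-3 replicates 1 and 2, 381 and 412 on cngc19 replicates 1 and 2, 82.0 on cngc1-3 replicate 3 and 3.77 on cngc19 replicate 3.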
